A study of Mus musculus with 9 samples.

How the data were processed

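RNA was profiled on 9 Affymetrix Mouse Genome 430 2.0 arrays, a platform named here from the probe annotation table. The arrays fell into 3 groups of 3 by their titles: ZsG minus cTEC, ZsG minus mTEC and ZsG plus. ZsGreen (ZsG) is a green fluorescent protein, and cTEC and mTEC are the usual abbreviations for cortical and medullary thymic epithelial cells. Per the labels' protocols, the mice were 8 to 20 weeks old and carried a bacterial artificial chromosome with the reporter at the start codon of Tslp. RNA was purified on spin columns and treated with DNase, and 5 ng was amplified with an Ovation Pico kit, per the labels' protocols. The sort markers and gates are not given in the sources used here, and neither is whether ZsG plus cells were sorted from cortical or medullary epithelium. The cell type field reads keratinocytes for all 9 samples, which differs from the titles; the groups follow the titles.

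The deposited values were probe set intensities on a linear scale, 1 column per array and 45101 probe sets per column. The software and settings that made them are not given in the sources used here. Tested on the values, the mean of each column with 2% removed at each end was 1250, so the authors' deposited intensities had been scaled to a common trimmed mean. Such scaling fixes the mean of every array and leaves its median and the width of its distribution free. No detection calls were analysed here, so dim values are given as measured. The number of arrays limits the precision.

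Intensities were taken to log2 with no offset. Gene names came from the annotation table: 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of the probe sets with 1 symbol, 34754 had a gene identifier found in the RefSeq gene table of the mouse assembly GRCm38.p6, used for names only, and 0 of these carried another symbol there. Only probe sets with 1 symbol were named or tested, and for the 9012 genes with several probe sets the one with the highest mean over the 9 arrays was used. This left 18194 genes. No pair of arrays held identical values.

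Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, with 1 coefficient per group over all 9 arrays and a shared estimate of the spread. The residual degrees of freedom were 6 and the prior degrees of freedom 3.28. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05 and no fold limit. Errors written after ± are standard errors of the log2 difference from this fit unless called SD, and levels are geometric means of intensity over the 3 arrays of a group. No label says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

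The design, the gene lists, the rule for naming genes and all but 1 of the alternatives were fixed before the data were examined. The 25 lists had 482 members, or 455 distinct genes, of which 413 were measured, 4 of them through an older symbol, and 41 were not matched. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation and with fry. Camera sets the members of a list against all other genes, while fry tests them against no change, so a shift common to all genes counts in fry. Genes named are Tslp, the 10 largest rises and falls past the threshold with fully separated groups, and for each list up to 4 members past the threshold in each direction and up to 2 of the brightest members not past it. Unnamed clones, olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments and small RNA genes were passed over in the ranking of rises and falls. Genes named by this rule in 1 comparison are also quoted in the others. Figures were drawn with matplotlib 3.10.9.

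The steps were tested on simulated data with the measured spread of each group. For ZsG plus versus ZsG minus mTEC, among 18194 simulated genes, 84.0% of 50 genes changed by 6 on the log2 scale were recovered, 34.0% of 50 changed by 4 and 0 of 50 changed by 2, while 12 unchanged genes were called. For ZsG plus versus ZsG minus cTEC these shares were 88.0%, 42.0% and 4.0%, with 19 unchanged genes called. For ZsG minus mTEC versus ZsG minus cTEC they were 82.0%, 48.0% and 0%, with 0 unchanged genes called. In this last comparison a simulated list of 20 genes shifted by 1.5 was called by camera, as was 1 of 24 unshifted lists. The simulated genes were drawn independently of each other. The simulation therefore cannot show how camera with a preset correlation performs where the members of a list vary together. No list was simulated for the ZsG plus comparisons. Changes of 2 or less on the log2 scale were thus mostly beyond reach for single genes.

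Alternatives changed 1 choice at a time: all probe sets with 1 symbol or all probe sets tested, a filter at the 40th percentile of mean intensity, repeated quantile normalization, centring of each array on its median, 16 added before log2, a trended and robust prior, array weights, a fit of only the 6 arrays compared, the replicate number as a block, a log2 limit of 1, and each array left out in turn. Centring each array on the median of the genes tested was added after seeing the data. Coordinates and sequences were not used here.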

Results

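The arrays compared reporter-positive thymic cells with reporter-negative cortical and medullary epithelium, which asks in what their expression differs. The reporter was placed at the start codon of Tslp, which encodes thymic stromal lymphopoietin, a cytokine made by epithelial cells. Whether reporter signal follows the Tslp transcript is not settled by these arrays. Each group had 3 arrays. Median intensity over all probe sets was 404, 382 and 376 on the ZsG minus cTEC arrays, 366, 369 and 424 on the ZsG minus mTEC arrays, and 259, 316 and 230 on the ZsG plus arrays. The ZsG plus arrays also varied most among themselves: the median SD of a gene within the group was 1.30 on the log2 scale, against 0.63 in ZsG minus mTEC and 0.61 in ZsG minus cTEC. Across genes, which are not independent replicates, Pearson's r between arrays of a group was 0.584 to 0.656 in ZsG plus, 0.808 to 0.820 in ZsG minus mTEC and 0.823 to 0.865 in ZsG minus cTEC. Between groups, r was 0.607 to 0.718 (mean 0.673) for ZsG plus with ZsG minus mTEC arrays. For ZsG plus with ZsG minus cTEC arrays it was 0.588 to 0.686 (mean 0.650). Between the ZsG minus groups it was 0.743 to 0.772. Both ranges for ZsG plus with another group lay below the range between the ZsG minus groups. They also overlapped the range within ZsG plus. By r, distance from the other groups thus cannot be told apart from poor agreement among the ZsG plus arrays. The ratio of 3' to 5' Gapdh signal, a measure of RNA integrity and amplification length, was 10.6, 6.71 and 8.21 on the ZsG plus arrays and 4.55 to 5.97 on the others. The same ratio for beta-actin did not separate the groups, at 1.09, 0.796 and 1.21 on the ZsG plus arrays and 0.874 to 1.14 on the others. Lower RNA integrity in ZsG plus is thus not settled.

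**Figure D1:**
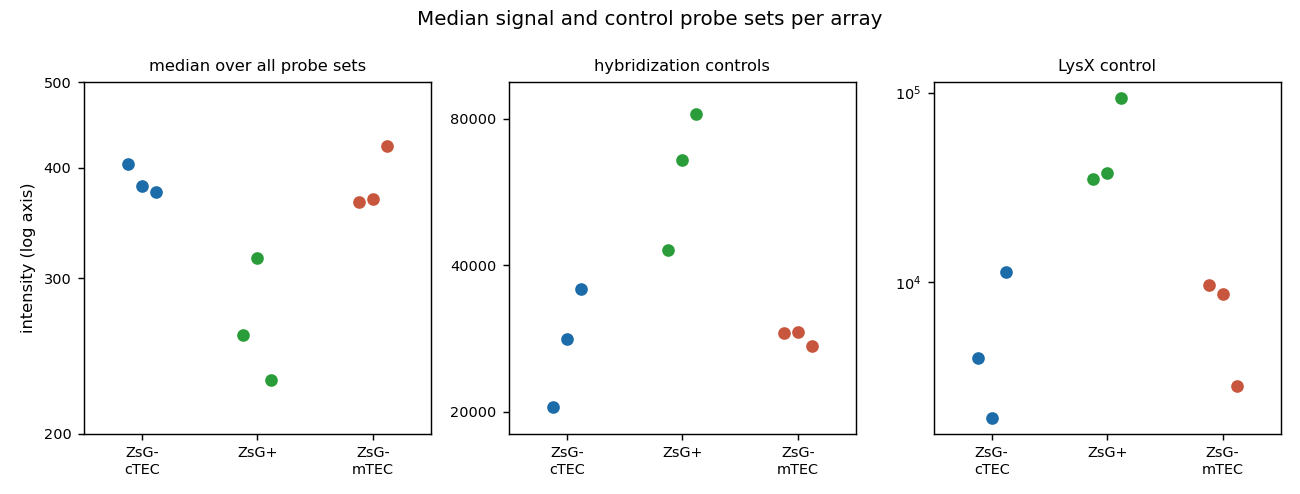
Intensity on each array, on a log axis with 3 points per group, of the median over all probe sets, of the hybridization controls (geometric mean of 9 probe sets) and of the LysX control (3 probe sets). The ZsG plus arrays had the lowest medians, 230 to 316, and the brightest controls.

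Tslp itself was not distinguishable among the groups. Its only probe set read 526, 23.4 and 953 on the ZsG plus arrays, 244, 472 and 359 on the ZsG minus mTEC arrays, and 264, 88.8 and 576 on the ZsG minus cTEC arrays. The readings of 23.4 and 88.8 lie within 7.91 to 170, the range of the bacterial control probe sets PheX and DapX. Tslp was thus near background on those arrays, and a lack of difference is not established. The log2 difference of Tslp was −0.61 ± 1.30 between ZsG plus and ZsG minus mTEC (limma adjusted p = 0.864) and −0.07 ± 1.30 between ZsG plus and ZsG minus cTEC (limma adjusted p = 0.983). Between the reporter-negative groups Tslp differed by 0.54 ± 1.30 (limma adjusted p = 0.959). The ZsG plus arrays spread over an SD of 2.87 for Tslp, so a difference of a few fold was not detectable here.

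**Figure D2:**
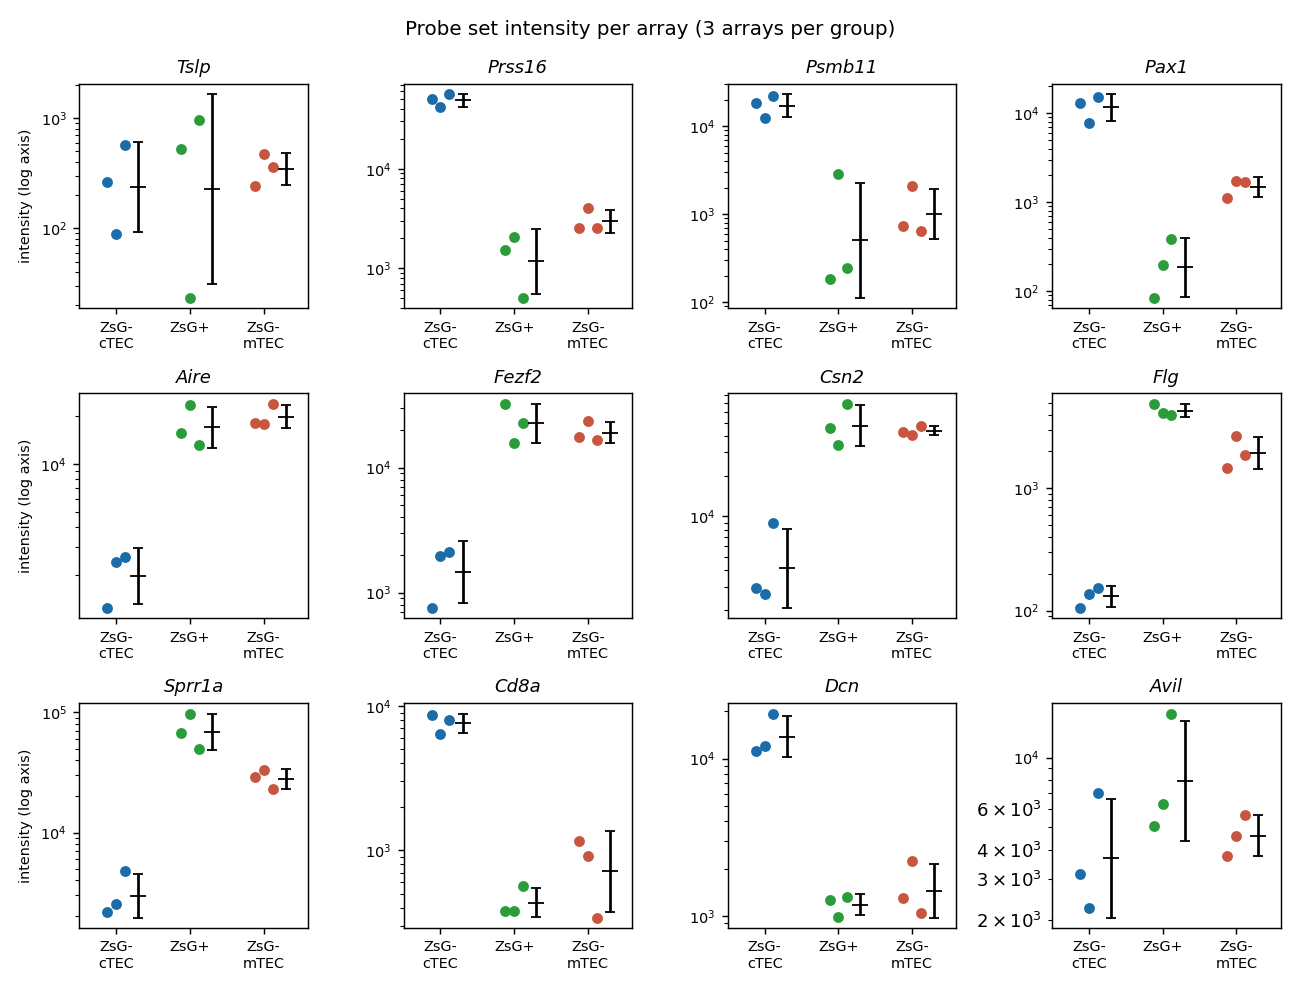
Intensity of 12 named genes on each array, on a log axis, with 3 points per group and, beside them, the geometric mean with bars of 1 SD on the log2 scale. Prss16, Psmb11 and Pax1 were lower in ZsG plus than in ZsG minus cTEC, Aire, Fezf2, Csn2, Flg and Sprr1a were higher, and the Tslp points of the 3 groups overlapped.

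The regulators that mark mature medullary epithelium were not distinguishable between ZsG plus and ZsG minus mTEC. Aire, which drives expression of tissue-restricted genes in the thymus, had a level of 16990 in ZsG plus and 19854 in ZsG minus mTEC, a log2 difference of −0.22 ± 0.55 (n = 3 arrays per group here and below). Fezf2, the other main regulator of such genes, stood at 22682 and 19026, a difference of 0.25 ± 0.61. The antigens Csn2, a milk casein, and Fabp9, a fatty acid binding protein of the testis, differed by 0.13 ± 0.63 and 0.27 ± 0.66. The list of 24 tissue-restricted antigens lay lower, with a median of −0.96, or −0.63 relative to all genes, and was not called (camera adjusted p = 0.157). Adjusted over the list alone, 1 member was lower and 0 were higher. The cortical genes Prss16, a thymic serine protease, and Psmb11, the thymoproteasome subunit, differed by −1.34 ± 0.64 and −0.98 ± 1.03. None of these 6 genes passed the threshold (limma adjusted p from 0.410 to 0.948).

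Across all genes, 3 were higher and 37 were lower in ZsG plus than in ZsG minus mTEC. The genes that fell included Lrwd1, which encodes a partner of the origin recognition complex, by 6.26 ± 0.77 on the log2 scale, from 3143 to 41.0. Enho, which encodes the secreted peptide adropin, fell by 6.11 ± 0.64, and Cdk5, a kinase best known from neurons, fell by 6.11 ± 0.74. Htra1, a secreted serine protease, the neurofilament gene Nefm, the kinase gene Map3k9 and the autophagy receptor gene Calcoco2 also fell, at −5.64 ± 0.76, −5.42 ± 0.67, −5.64 ± 0.62 and −5.26 ± 0.69. Omt2b, Prp2 and Bcat1 fell too, at −6.19, −5.88 and −5.78. Tmem100, a transmembrane protein gene, rose by 4.66 ± 0.67, from 12.3 to 313, although only 1 of its 2 probe sets showed this sign; 1 probe set each of Enho, Cdk5, Bcat1 and Map3k9 also went against the others. Pdcd1, which encodes the inhibitory receptor PD-1, rose by 4.25 ± 0.52, from 9.86 to 187, and the uncharacterised 4930549C15Rik, named after its values were seen, rose by 3.96 ± 0.61. The ZsG minus cTEC arrays read 136, 84.1 and 147 for Pdcd1 and 141, 127 and 65.0 for Tmem100. Neither of these genes was called higher in ZsG plus than in ZsG minus cTEC. In 38 of these 40 genes the dimmer group lay below an intensity of 100, the range of bacterial control probe sets for PheX and DapX, which read 7.91 to 170 on these arrays, so the size and order of these differences are not settled. Over the alternatives Tmem100 ran from 3.50 to 5.29 and Pdcd1 from 2.97 to 4.87. The median over all genes was −0.33, so falls of this size exceed a common shift. Adjusted p-values of the 40 genes were at least 0.030 (limma, Benjamini-Hochberg), and 582 genes higher and 1855 lower had an unadjusted p under 0.05, or 1696 higher and 870 lower after centring on the genes tested. The split of 7.5% higher became 26.7% with repeated quantile normalization and 33.3% with either centring, where 15 and 3 genes passed. In a limma fit of only the 6 arrays, or with array weights, 0 genes passed (1785 and 1705 at an unadjusted p under 0.05), and leaving out any 1 ZsG minus array left at most 7.

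No member of the 25 lists passed the threshold over all genes in limma between ZsG plus and ZsG minus mTEC. Epidermal genes with separated groups but no call included Flg, the filaggrin gene, at 4320 against 1940 (1.15 ± 0.51), and Sprr1a, a cornified envelope gene, at 68945 against 28078 (1.30 ± 0.56). As a list the 28 epidermal differentiation genes had a median difference of −0.08, with 0 members past the threshold over all genes, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. The 15 measured genes of the NF-kappaB pathway had a median of 0.43, or 0.75 relative to all genes, and camera called the list higher (adjusted p = 0.0189; adjusted p = 0.780 with an estimated correlation and 0.205 with fry). Its brightest members Nfkbia and Icam1 differed by 0.67 ± 0.50 and 0.36 ± 0.51. The 17 dendritic cell and macrophage markers had a median of 0.62, or 0.95 relative to all genes, and were also called by camera (adjusted p = 0.0189; adjusted p = 0.780 with an estimated correlation and 0.401 with fry), with 1 member higher adjusted over the list alone. Leaving out ZsG plus replicate 1 or replicate 3 left 0 lists called. The macrophage genes Lyz2 and C1qb differed by 0.04 ± 0.71 and 0.62 ± 0.72. The 7 erythroid markers had a median of −2.14, with 3 members lower adjusted over the list alone and an adjusted p of 0.157 with camera and 0.0109 with fry. The 29 tuft cell genes had a median of −0.48 and 0 members past the threshold, 2 lower at an unadjusted p under 0.05, and their bright members Trpm5 and Avil differed by 0.65 ± 0.71 and 0.78 ± 0.66.

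Against ZsG minus cTEC, ZsG plus cells had less of the cortical genes Prss16, Psmb11, Pax1 and Enpep and more of the medullary regulators Fezf2 and Aire. Prss16 fell by 5.38 ± 0.64 on the log2 scale, from 48742 to 1173, and Psmb11 fell by 5.09 ± 1.03, from 17157 to 504. Pax1, a transcription factor of thymus development, fell by 5.97 ± 0.67, and Enpep, which encodes an aminopeptidase often used as a cortical sort marker, fell by 6.78 ± 0.95. Of the 16 measured cTEC markers, 4 were lower over all genes tested, and 10 were lower and 1 higher adjusted over the list alone. The list median was −2.43, or −2.29 relative to the median of −0.14 over all genes, and camera called it lower (adjusted p = 2.39e-05; adjusted p = 0.0568 with an estimated correlation). Its bright members Krt18, an epithelial keratin, and Ccl25, a thymic chemokine, differed by 0.34 ± 0.54 and −1.16 ± 0.50 and did not pass. Of the 15 genes of the mature mTEC and Aire programme, Fezf2 rose by 3.96 ± 0.61, Aire by 3.11 ± 0.55 and the histidine decarboxylase gene Hdc by 2.77 ± 0.54, while the chemokine gene Ccl17 fell by 3.72 ± 0.75; this list was not called (camera adjusted p = 0.217), with 4 higher and 1 lower adjusted over the list alone. Bright Ctss, a lysosomal protease gene, differed by −0.09 ± 0.52.

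Of 28 epidermal differentiation genes, 9 were higher in ZsG plus than in ZsG minus cTEC over all genes tested and 18 adjusted over the list alone. Flg rose by 5.05 ± 0.51, from 131 to 4320, Sprr1a by 4.53 ± 0.56, from 2977 to 68945, and the involucrin gene Ivl and the keratin gene Krt77 by 4.53 ± 0.87 and 4.41 ± 0.84. The list median was 2.69, or 2.82 relative to all genes (camera adjusted p = 2.71e-16; adjusted p = 0.0568 with an estimated correlation). Of 24 tissue-restricted antigens 6 were higher, and 12 were higher and 1 lower adjusted over the list alone, with a median of 2.12 (camera adjusted p = 4.92e-09; adjusted p = 0.0671 with an estimated correlation). Examples are the salivary gene Mucl2 (4.19 ± 0.84), the Purkinje cell gene Pcp4 (3.75 ± 0.67), Csn2 (3.53 ± 0.63) and Fabp2 (3.27 ± 0.51). Of 16 microfold and enterocyte genes, Muc1 (3.31 ± 0.64), Fabp2 and the antimicrobial lectin gene Reg3g (3.04 ± 0.53) rose, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.07e-06; adjusted p = 0.0895 with an estimated correlation). The last 2 of these genes also belong to the antigen list. The 19 claudin and junction genes had a median of 1.00 (camera adjusted p = 0.00175; adjusted p = 0.0895 with an estimated correlation), with 0 members past the threshold over all genes, 3 higher adjusted over the list alone and 6 at an unadjusted p under 0.05.

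Among 6 lists of markers of other cells, camera called those of thymocytes and fibroblasts lower in ZsG plus than in ZsG minus cTEC and left the other 4 uncalled (adjusted p from 0.200 to 0.880). Of 18 thymocyte and T cell markers, Cd8a fell by 4.13 ± 0.61, from 7574 to 434, and Dntt, the terminal transferase of immature lymphocytes, fell by 5.36 ± 0.88. Adjusted over the list alone, 10 of them were lower, and the list median was −2.72 (camera adjusted p = 3.11e-06; adjusted p = 0.0671 with an estimated correlation). Bright Cd247 and Satb1 differed by −0.49 ± 0.66 and −1.67 ± 0.65 and did not pass over all genes. Of 12 fibroblast markers the matrix gene Dcn fell by 3.54 ± 0.55, from 13779 to 1182, although 1 of its 2 probe sets showed the opposite sign, and 6 were lower adjusted over the list alone, with a median of −2.50 (camera adjusted p = 0.000276; adjusted p = 0.0895 with an estimated correlation). The 21 cell cycle genes had a median of −1.67 (camera adjusted p = 0.000427; adjusted p = 0.167 with an estimated correlation), with 0 members past the threshold over all genes, 1 lower adjusted over the list alone and 9 at an unadjusted p under 0.05. Mki67 and Pcna, both marks of dividing cells, differed by −0.36 ± 0.67 and −0.52 ± 0.63.

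In all, 109 genes were higher and 208 lower in ZsG plus than in ZsG minus cTEC, with adjusted p-values of 0.00781 or more (limma, Benjamini-Hochberg). In 155 of these 317 genes the dimmer group lay below an intensity of 100, so the size and order of such differences are not settled, here or among the list members above. The largest rises at the values used were in Alox12b, a lipoxygenase of the epidermal barrier (7.01 ± 0.83), the mucosal glycoprotein gene Dmbt1 (6.10 ± 0.83) and Aox4, Rnase2a, Nkd2 and the keratinocyte gene Kprp at 6.04, 5.99, 5.98 and 5.75. Rnase2a and Kprp started from levels of 2.64 and 7.04, below the range of the PheX and DapX controls, and over the alternatives their rises ran from 3.42 to 7.26 and from 4.10 to 6.29. Serpina10, Hao2, Gdpd3 and Pmp2 followed at 5.72, 5.47, 5.41 and 5.41, and 1 of the 4 probe sets of Nkd2 went against the rest. The largest falls were in the uroplakin gene Upk3b, by 7.83 ± 0.63, from 6893 to 30.4, the sphingosine phosphate receptor gene S1pr3, at −7.73 ± 1.04, and Gas1, at −7.64 ± 0.85. Rapgef3, Fkbp9, the leukocyte surface gene Cd48, Lrwd1, the lysophosphatidic acid receptor gene Lpar1 and the parathyroid hormone gene Pth fell as well, at −7.50, −7.22, −7.19, −6.86, −6.86 and −6.69. Among lists without a call, the Notch ligand gene Dll1 (−3.52 ± 0.55), the stress gene Ier3 (−2.70 ± 0.54) and Rpl14, of the ribosomal proteins (−6.12 ± 1.12), fell, the last with an SD of 2.46 over the ZsG plus arrays. The split of 34.4% higher became 53.2% with repeated quantile normalization, 63.6% with each array centred on its median and 58.3% with centring on the genes tested. In a limma fit of only the 6 arrays 0 genes passed (2704 at an unadjusted p under 0.05), 37 passed with array weights, and leaving out ZsG minus cTEC replicate 1 or replicate 2 left 0, with 2467 and 2437 at an unadjusted p under 0.05.

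**Figure D3:**
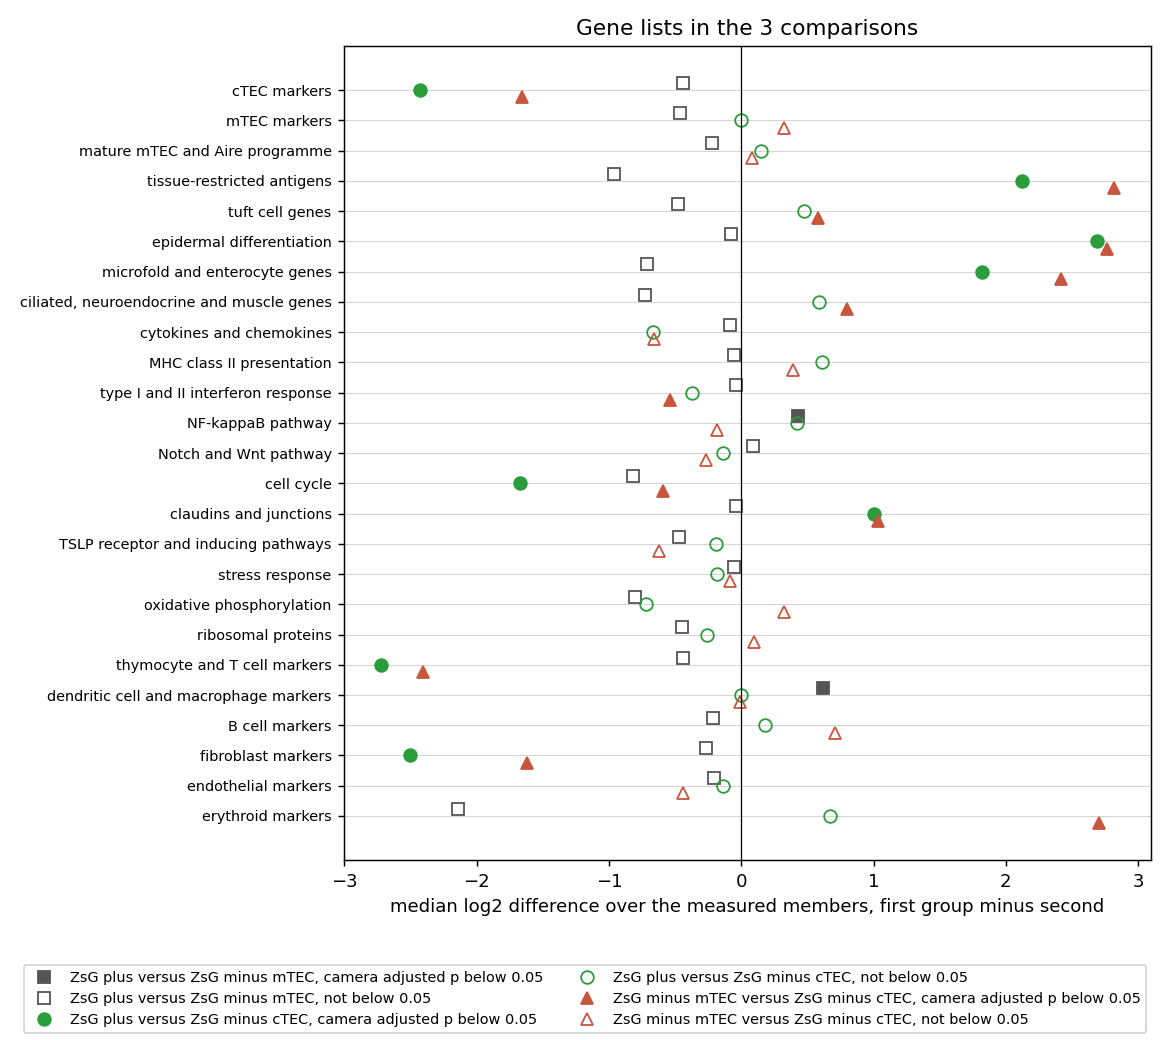
Median log2 difference over the measured members of each of 25 gene lists, 1 symbol per comparison, filled where camera with a preset correlation gave an adjusted p below 0.05. The epidermal and tissue-restricted lists lay at 2.69 and 2.12 for ZsG plus versus ZsG minus cTEC and at −0.08 and −0.96 for ZsG plus versus ZsG minus mTEC.

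The reporter-negative groups differed from each other in several genes that separate medulla and cortex. Fezf2 was higher in ZsG minus mTEC by 3.70 ± 0.61, Aire by 3.33 ± 0.55 and Hdc by 3.59 ± 0.54. Prss16 was lower, falling by 4.04 ± 0.64, from 48742 to 2963, and so was Cd83, a surface protein of cortical epithelium and dendritic cells, which fell by 3.18 ± 0.52. Of 16 cTEC markers 2 were lower, 7 adjusted over the list alone, with a median of −1.66 (camera adjusted p = 2.16e-07; adjusted p = 0.0219 with an estimated correlation). Of the mature mTEC and Aire programme 3 were higher, 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.396 with camera and 0.0435 with fry). The keratin genes Krt5 and Krt17, from 12 general mTEC markers, differed by −0.03 ± 0.70 and 1.25 ± 0.53, and that list had a median of 0.32 (camera adjusted p = 0.408).

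Among the lists of epithelial genes, those of antigens and epidermal genes had the highest medians. Of 24 tissue-restricted antigens, Mucl2 (5.60 ± 0.84), Pcp4 (4.90 ± 0.67), Fabp2 (3.97 ± 0.51) and the trypsin inhibitor gene Spink1 (3.18 ± 0.52) were higher in ZsG minus mTEC, 16 adjusted over the list alone, with a median of 2.82 (camera adjusted p = 1.19e-17; adjusted p = 0.0219 with an estimated correlation). Of 28 epidermal genes 5 were higher, 20 adjusted over the list alone, among them the desmoglein gene Dsg1a (4.42 ± 0.63), Krtdap (4.03 ± 0.62), Flg (3.89 ± 0.51) and Spink5 (3.81 ± 0.63), with a median of 2.77 (camera adjusted p = 4.03e-18; adjusted p = 0.0219 with an estimated correlation). Of 16 microfold and enterocyte genes Fabp2 and the chemokine gene Ccl20 (3.15 ± 0.55) were higher, 10 adjusted over the list alone, with a median of 2.42 (camera adjusted p = 6.22e-08; adjusted p = 0.0531 with an estimated correlation). The 19 claudin and junction genes had a median of 1.03 (camera adjusted p = 0.00343; adjusted p = 0.0773 with an estimated correlation) and 1 member higher adjusted over the list alone. The 20 ciliated, neuroendocrine and muscle genes had a median of 0.80 (camera adjusted p = 0.0142; adjusted p = 0.0681 with an estimated correlation) and 4 members higher adjusted over the list alone. The 29 tuft cell genes had a median of 0.58 (camera adjusted p = 0.0462; adjusted p = 0.373 with an estimated correlation and 0.0751 with fry) and 0 members past the threshold in limma, 3 at an unadjusted p under 0.05; Trpm5 and Avil differed by 0.50 ± 0.71 and 0.32 ± 0.66.

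Beside these, the 18 thymocyte and T cell markers were lower in ZsG minus mTEC, with a median of −2.40 and 8 members lower adjusted over the list alone (camera adjusted p = 1.53e-09; adjusted p = 0.0219 with an estimated correlation). Over all genes tested, Cd8a alone of them passed and fell by 3.41 ± 0.61. Of 12 fibroblast markers Dcn fell by 3.26 ± 0.55, and 4 were lower adjusted over the list alone, with a median of −1.62 (camera adjusted p = 1.19e-05; adjusted p = 0.0521 with an estimated correlation). Of 7 erythroid markers Epb42, a red cell membrane protein gene, rose by 3.91 ± 0.58, and 2 were higher adjusted over the list alone, with a median of 2.70 (camera adjusted p = 0.000346; adjusted p = 0.0350 with an estimated correlation). Flt3, of the dendritic cell markers, fell by 4.27 ± 0.74, and Plvap, of the endothelial markers, rose by 5.66 ± 0.88, from 6.26 to 316, while neither list was called (camera adjusted p = 0.152 and 0.970). The level of 6.26 lies below the range of the PheX and DapX controls, so the size of the rise in Plvap is not settled, and over the alternatives it ran from 3.85 to 6.45. The 19 interferon response genes had a median of −0.54 (camera adjusted p = 0.00648; adjusted p = 0.0531 with an estimated correlation) and the 21 cell cycle genes one of −0.59 (camera adjusted p = 0.00588; adjusted p = 0.236 with an estimated correlation and 0.165 with fry). Each of these lists had 0 members past the threshold in limma, and 2 and 1 lower at an unadjusted p under 0.05.

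In all, 96 genes were higher and 18 lower in ZsG minus mTEC than in ZsG minus cTEC, with adjusted p-values of 0.0275 or more (limma, Benjamini-Hochberg). The largest rises at the values used were in Gje1, Rnase2a, Alox12b, Svs4, Cst10 and Hba-x, at 7.74, 7.61, 7.54, 7.09, 6.47 and 6.44. Their levels in ZsG minus cTEC were 1.08 to 19.4, within or below the range of the PheX and DapX controls, so size and order are not settled: over the alternatives Gje1 ran from 3.84 to 8.33, Rnase2a from 4.84 to 8.02 and Alox12b from 6.66 to 7.86. In 51 of the 114 genes, list members among them, the dimmer group lay below 100, and the same limit holds. Omt2b, Tmsb15a, Tmem45a2 and the olfactory channel gene Cnga2 rose by 6.32, 6.10, 6.00 and 5.94. The largest falls were in Rab43 (−6.17 ± 1.03), the plexin gene Plxnc1 (−5.45 ± 0.73, with the same sign on all 6 of its probe sets), Colgalt2 (−4.84 ± 0.66) and Inmt (−4.67 ± 0.83). Myo1f, Diras2, Klf15 and the intermediate filament gene Synm fell too, at −4.19, −4.16, −3.85 and −3.84. A limma fit of only these 6 arrays called 548 genes, and array weights called 1220. Leaving out any 1 of the 6 ZsG minus arrays left 0 genes, with at least 1697 at an unadjusted p under 0.05. Those fits share 1 spread per gene with the ZsG plus arrays, whose median SD was 1.30 against 0.63 and 0.61. The counts of 0 hold for that shared spread, and no array was left out of the fit of only 6 arrays.

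Setting the groups side by side, ZsG plus lay closer to ZsG minus mTEC than to ZsG minus cTEC for 75 of the 96 genes higher in ZsG minus mTEC (78.1%) and for 11 of the 18 lower genes (61.1%). For lower genes the share was 40% with either centring and 50% with all probe sets tested. Genes are not independent replicates, and this share was not tested. The mean r of ZsG plus arrays was 0.673 with ZsG minus mTEC and 0.650 with ZsG minus cTEC arrays, with overlapping ranges. With all 3 groups in 1 test, limma's F test called 213 genes. It called 0 with the replicate number as a block or without ZsG minus cTEC replicate 1, ZsG minus cTEC replicate 2 or ZsG minus mTEC replicate 1 (2422 to 3085 at an unadjusted p under 0.05), and 7 to 16 without another ZsG minus array. A set of 29 genes was lower in ZsG plus than in both other groups, among them Lrwd1, Enho, Cdk5, Map3k9, Htra1, Nefm, Cd48, Lpar1 and Upk3b. Independent lists would share 0.423 genes. Simulated unchanged groups of equal spread shared 0 in each of 100 draws, and how many genes those draws called was not kept. Separate draws with the measured spread of each group called almost no genes, 0.07 and 0.03 lower ones on average. A shared count of 0 in unchanged groups thus says little. Both comparisons use the same ZsG plus arrays, which are too few to divide, so part of the overlap may come from them. By limma 0 genes were higher in ZsG plus than in both other groups, and 190 were so at an unadjusted p under 0.05 in each comparison. The groups were fully separated for 18.1%, 23.3% and 28.5% of genes in the comparisons of ZsG plus with ZsG minus mTEC, ZsG plus with ZsG minus cTEC, and the ZsG minus groups, where chance gives 10%. The first group lay above for 1050, 1802 and 3022 genes and below for 2239, 2435 and 2155. In the first comparison the larger count went with the median of −0.33 over all genes, so array scaling cannot be told apart from other causes of the excess there.

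As lists, genes of antigen presentation and of several general pathways were not called by camera in any comparison. With fry, which unlike camera tests a list against no change and so includes any shift common to all genes, MHC class II presentation (adjusted p = 0.0137), ribosomal proteins (0.0158), oxidative phosphorylation (0.0386) and the Notch and Wnt pathway (0.0386) were called between ZsG plus and ZsG minus cTEC. So was the interferon response, with a median of −0.37, 1 member higher and 5 lower at an unadjusted p under 0.05 in limma, and an adjusted p of 0.200 with camera and 0.00922 with fry. By fry but not camera, oxidative phosphorylation (adjusted p = 0.0109) and ribosomal proteins (0.0233) were also called between ZsG plus and ZsG minus mTEC, where their medians relative to all genes were −0.48 and −0.12, and MHC class II presentation (0.0396) between the ZsG minus groups. Cd74 and H2-Aa, which present antigen on MHC class II, differed by 1.17 ± 0.49 and 0.79 ± 0.48 between ZsG plus and ZsG minus cTEC, and by 0.80 ± 0.49 and 0.31 ± 0.48 between ZsG plus and ZsG minus mTEC. In the comparison of ZsG plus with ZsG minus cTEC, the list median was 0.61 for MHC class II presentation, −0.67 for cytokines and chemokines, −0.14 for the Notch and Wnt pathway and −0.19 for the TSLP receptor and inducing pathways. It was −0.18 for the stress response, −0.72 for oxidative phosphorylation, −0.26 for ribosomal proteins, 0.18 for B cell markers and −0.14 for endothelial markers. Camera's adjusted p for these 9 lists was 0.129 or more in that comparison.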

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

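The tests of the control probe sets were chosen after their levels had been seen. Of 8 families of control probe sets, 4 were brighter on every ZsG plus array than on every ZsG minus array. The alternative that tested all probe sets included these controls. The hybridization controls BioB, BioC, BioDn and CreX, bacterial and phage sequences added to the labelled sample, were 2.20-fold brighter. The bacterial control LysX was 9.53-fold brighter, ThrX 8.13-fold and 18S ribosomal RNA 1.91-fold. Chance alone puts all 3 ZsG plus arrays above the other 6 with an exact one-sided probability of 0.0119 for each control. In the other 4 the ranges overlapped, with ratios of 2.23 for PheX, 2.17 for DapX, 1.39 for beta-actin and 0.983 for Gapdh.

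The hybridization controls rose by nearly the same factor, with a range of 0.154 on the log2 scale over the 4 of them. Less labelled sample on the ZsG plus arrays, scaled up to the common trimmed mean, may account for that part. Scaling does not account for LysX: divided by the hybridization controls, it was still 2.12 higher on the log2 scale in ZsG plus, with shares of 57.5 to 114% against 6.83 to 33.4% on the other arrays. A LysX control added before amplification of a smaller amount of RNA would rise in this way, but the labels do not say when it was added, and this was not tested. No biological explanation was tested: the added controls do not come from the cells, while 18S ribosomal RNA does, and a difference between the cells stays open for it.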

How the results depend on the processing

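Centring each array on the median of the genes tested was chosen after seeing the data; all other alternatives were planned. Counts are given as higher and lower for ZsG plus versus ZsG minus mTEC, then ZsG plus versus ZsG minus cTEC, then ZsG minus mTEC versus ZsG minus cTEC, and the cause of a move was not tested. The 95 values of called genes named in the text kept their sign in all 1877 refitted values and passed the threshold in 986. These genes were chosen for large differences in the same data, and each refit used the same probe set, so a kept sign says little. Their other probe sets were not counted, and some had the opposite sign. Other results turned: with repeated quantile normalization or either centring more genes were higher than lower in the ZsG plus versus ZsG minus cTEC comparison, at 141 and 124, 185 and 106, and 158 and 113, against 109 and 208. Testing all probe sets with 1 symbol gave 6 and 76, a fall count of 412 in the next, and 36 and 7, with 62 lower than both groups and 331 in the F test. Testing all probe sets, controls included, gave 6 and 60, falls of 316, and 12 and 2, with 48 lower than both. In both of these settings the counts are of probe sets and not of genes. The filter on dim probe sets gave 0 rises in the first comparison, 179 and 349 in the next, and 433 in the F test. Quantile normalization gave falls of 11 and 124, then 149 and 29, with 1 gene higher and 6 lower than both groups and 4 lists called in the first comparison. Centring on the array median gave 1 and 2, 185 and 106, and 61 and 10, with 2 lower than both and 1 list. Centring on the genes tested gave 1 and 2, falls of 113, and 38 and 10, with 2 lower than both and 1 list. Adding 16 before log2 gave falls of 337, then 161 and 30, and 461 in the F test. The trended and robust prior gave 0 and 14, 260 and 333, and 229 and 36, with 13 lower than both and 507 in the F test. Array weights, which were 0.268 to 0.489 for ZsG plus arrays and 1.12 to 2.24 for the others, gave 0 and 0, 6 and 31, and 879 and 341, with 0 lower than both, 790 in the F test and 66.6% of the higher genes closer to ZsG minus mTEC. Fits of only 6 arrays gave 0 and 0, 0 and 0, and 395 and 153. Camera with an estimated correlation called 0, 0 and 5 lists, and fry, which tests against no change and not against other genes, called 3, 13 and 12. In the first comparison fry called the erythroid, oxidative phosphorylation and ribosomal lists and neither list called by camera. The share of lower genes closer to ZsG minus mTEC went from 61.1% to 40% with either centring and to 50% with all probe sets tested.

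With the replicate number as a block limma gave 0 and 0, 3 and 13, and 0 and 0, with 0 lower than both groups and 0 in the F test (2320 and 2172 genes at an unadjusted p under 0.05 in the first and last comparisons). Deviations of same-numbered arrays correlated at −0.0150 to 0.0132 and those of other arrays at −0.0224 to 0.0114, so the numbers gave no sign of pairing.

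Leaving out 1 array at a time gave 0 to 21 higher and 0 to 209 lower in the first comparison, 0 to 196 and 0 to 539 in the next, and 0 to 243 and 0 to 61 in the last. It gave 0 to 8 genes higher and 0 to 169 lower than both groups and 0 to 567 in the F test. Every low end came from leaving out a ZsG minus array and every high end from leaving out a ZsG plus array. Without ZsG plus replicate 1, 2 or 3, 230, 211 and 94 genes passed in the first comparison and 685, 735 and 474 in the next. Without ZsG minus cTEC replicate 3 these were 7 and 23. Lists called ranged over 0 to 2, 8 to 9 and 10 to 13. In these fits the share closer to ZsG minus mTEC was 65.0 to 76.1% for higher and 67.2 to 71.4% for lower genes, and had no value where no gene passed. Signal limits the comparisons too: 38 of 40, 155 of 317 and 51 of 114 called genes had a dimmer group under an intensity of 100.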

Other observations

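The tests of array scaling, of other probe sets, of the markers of other cells and of the epidermal genes were chosen after the results had been seen. The bright genes Ifit1, Insm1 and Dsp did not pass the threshold in limma in any comparison. Ifit1, an antiviral gene induced by interferon, had levels of 54754 in ZsG plus, 20891 in ZsG minus mTEC and 16789 in ZsG minus cTEC, while the interferon response list had a median of −0.37 for ZsG plus versus ZsG minus cTEC and −0.04 for ZsG plus versus ZsG minus mTEC. Insm1, a transcription factor of neuroendocrine cells, stood at 7124, 34570 and 10743 in the same order, with ZsG plus arrays from 1652 to 20939. The desmosome gene Dsp stood at 87507, 47299 and 41401.

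ZsG plus arrays had 37 genes lower and 3 higher than ZsG minus mTEC, and of the genes at an unadjusted p under 0.05 in limma 76.1% were lower. Array scaling cannot be told apart from other causes of this excess: the share was 33.9% after centring on the genes tested, which itself pulls the split towards balance, 40% after centring on the array median and 53.8% after repeated quantile normalization, and with the centring on genes 2 of the 37 stayed past the threshold as their median shrank from −4.91 to −4.29 at standard errors of 0.66 and 0.65. Independent losses of 2.73, 3.32 and 7.15% of bright genes would put 0.873 genes at a sixteenth or less on all 3 ZsG plus arrays. The count was 11, or 12.6 times that. All 3 arrays were set against the same ZsG minus mTEC mean, whose error is shared, and rates were matched by brightness only. The excess therefore does not exclude random loss. Of the 37 genes called lower, 10 were among the 11, and 33 genes met the same limit on all 3 ZsG minus cTEC arrays. Transcripts prone to loss also stay open. The wider ZsG plus spread alone gave as many falls in 0 of 100 simulated draws, with 3 at most, but once some genes change it adds false calls: in simulated arrays of the same spread 12 unchanged genes were called beside 17 and 42 of 50 genes changed by 4 and by 6 on the log2 scale. Failure of single probe sets cannot be told apart from a true fall, because the other 27 probe sets of 18 of these genes had a median of −0.71 against −0.43 over all, and only 2 of them were bright in ZsG minus mTEC, at −2.77 and −5.33; a difference between the cells stays open as well.

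Thymocyte and fibroblast markers were lower in ZsG minus mTEC than in ZsG minus cTEC. A loss of purity in ZsG minus cTEC alike for every other cell type would raise the markers of each of them there. The 7 erythroid markers went the other way, with a median of 2.70. These could also be raised in ZsG minus mTEC itself, and an impure sort need not hold every cell type, so impurity of ZsG minus cTEC is not excluded. Carried thymocytes in ZsG minus cTEC stay open and were not tested apart from the pattern itself: 94.4% of the 18 markers had a negative difference, which restates it, and 8 of the 18 were lower adjusted over the list alone. Their median level was 3162 in ZsG minus cTEC and 537 in ZsG minus mTEC, and the brighter ones in ZsG minus cTEC included Dntt at 13062 and Cd8a at 7574, with Rag1 at 15570 and Bcl11b at 7816 named after their values were seen. Cortical epithelium is known to enclose thymocytes as nurse cells, and enclosed cells, free thymocytes passing the sort and RNA from lysed cells were not separated by these tests.

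A hypothesis was that ZsG plus holds a larger share of cells with an epidermal programme than ZsG minus mTEC. The mean log2 value of the epidermal list less that of the antigen list was 0.22 ± 0.58 (SD, n = 3) in ZsG plus, −0.67 ± 0.08 in ZsG minus mTEC and −0.34 ± 0.18 in ZsG minus cTEC. The difference of 0.89 between the first 2 groups had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give, so the test could not decide. The part of each list depends on the scaling: the median differences of the epidermal and antigen lists were −0.08 and −0.96 at the deposited scaling and 0.54 and −0.33 after centring on the genes tested, so neither more epidermal nor less antigen expression in ZsG plus is settled.

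Other splits of the same arrays were refitted. The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. For ZsG plus versus ZsG minus mTEC the real split, 1 of the 10, called 40 genes and 2 lists, against at most 0 and 0 in another. For ZsG plus versus ZsG minus cTEC it called 317 genes and 8 lists, against at most 0 and 7. Between the ZsG minus groups it called 114 genes and 12 lists, against at most 0 and 9. Over 100 splits of the 9 arrays, the real one included, 1 gave as many as the 213 genes of the F test, with 4 as the next highest, and 1 gave as many as the 29 genes lower in ZsG plus than in both groups, with 2 as the next highest. If the 9 arrays are independent samples, 1 of 100 splits makes a chance division unlikely for a difference somewhere among the 3 groups. No label says that they are, and median signal, spread and controls also differed by group. The splits therefore do not trace the difference to the cells. The splits do not test ZsG plus against both others, since most of them mix ZsG minus cTEC with ZsG minus mTEC arrays and so widen the spread. By limma the count of 29, with 983 at an unadjusted p under 0.05 in each comparison, was 0 with array weights, with the replicate block and on leaving out any 1 of 5 of the 6 ZsG minus arrays. The F test's 213, with 3314 at an unadjusted p under 0.05, was 0 with that block and on leaving out any 1 of 3 ZsG minus arrays. What the splits show thus holds only for the fit of all 9 arrays. For genes higher than in both groups, 100 of 100 splits gave the real count of 0.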
